A study of Mus musculus with 17 samples.

How the data were processed

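Messenger RNA was measured in 17 libraries of stem cells that were sorted by flow cytometry from the skin of wild-type mice. Hair follicle stem cells (HFSCs) reside in the bulge of the follicle, and epidermal stem cells (EpiSCs) maintain the epidermis between follicles. The short fasting experiment held 3 HFSC libraries each from mice fed ad libitum, fasted for 24 h and fasted for 48 h, and 2 EpiSC libraries from mice fed ad libitum. EpiSCs of fasted mice were not analysed here. A long-term experiment held 2 HFSC libraries from mice on 6 months of alternate-day fasting, sampled the day after a fast, and 2 from mice fed ad libitum for 6 months. A further 2 HFSC libraries came from follicles in the 2nd telogen, the second resting phase of the hair cycle. Per the labels' protocols, RNA was purified with a column kit for small samples, and libraries were made with a kit for full-length amplification of mRNA from single cells followed by a transposase library kit. The surface markers used in the sort are not given in the sources used here.

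Groups were taken from the sample titles. For the fasted long-term libraries the title and description give alternate-day fasting while the treatment field reads ad libitum, and the title was followed. The EpiSC titles number the libraries 1 and 2 and the descriptions number them 2 and 3. The table with the telogen libraries also held 2 columns of ad libitum HFSCs, numbered 2 and 3, whose values were identical to those of ad libitum libraries 2 and 3 for 35674 of 35674 genes within 1e-06 TPM, and these were counted once. The names of both columns carry the prefix ana1, which the sources used here do not explain, and the labels give no hair cycle stage for the ad libitum HFSCs. Its column names do not say which telogen column is which telogen sample, so these libraries carry no replicate number.

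The deposited values were transcript abundances scaled to a fixed library total (TPM) for 35674 gene symbols, computed by the authors, and each library summed to 1e+06. Per the submitters' processing notes, Salmon 1.4.0, DESeq2 1.36.0 and the mm10 build were used for every library, with fastp 0.23.1 for the short fasting experiment and Trimmomatic 0.39 for the long-term and telogen libraries. The notes give no role or order for these tools. Since TPM holds no read counts, the sequencing depth of each library is unknown, no count model was used, and no counting interval or detection limit could be given. No scaling between libraries was visible in the values, and the long-term table shares no library with the others. Each test stayed within a table. Gene positions were taken from the GENCODE M21 annotation of GRCm38 (mm10), in which 35502 of the symbols had a single position.

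Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), using the empirical Bayes moderated test with a mean-variance trend, and all tests were two-sided. A gene entered a fit when its mean TPM over the libraries of the fit was at least 1. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was taken as a change. Every fold change is on the log2(TPM + 1) scale, which understates the change of genes with low values. The 9 HFSC libraries of the short experiment shared 1 fit for the comparisons of 24 h with ad libitum, 48 h with ad libitum and 48 h with 24 h. EpiSCs were compared with HFSCs in the 5 ad libitum libraries, long-term fasting with long-term feeding in 4 libraries, and telogen with ad libitum HFSCs in the 4 libraries of their table. The labels do not say that replicates came from separate mice, so p-values measure the spread between these samples, which may be technical.

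Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, which asks whether the members of a list move in 1 direction without comparing them with other genes, were run as alternatives. The 30 lists were hair follicle stem cell identity; interfollicular epidermis and upper follicle; epidermal differentiation; stress keratinocyte; fatty acid oxidation; PPAR targets of fasting; lipid storage and lipolysis; fatty acid synthesis; cholesterol synthesis; glycolysis; the TCA cycle; oxidative phosphorylation; cytosolic ribosomal proteins; ribosome biogenesis with MYC targets; glucocorticoid response; cAMP and CREB response; immediate early and dissociation; FOXO targets with autophagy; integrated stress response; unfolded protein response; antioxidant and NRF2 targets; p53 targets with apoptosis effectors; anti-apoptotic; cell cycle; Wnt and hedgehog activation; BMP response and quiescence; circadian clock; interferon response; matrix and adhesion of basal cells; and mitochondrially encoded genes. Markers of fibroblasts, immune cells, endothelium, melanocytes, sebocytes, adipocytes, muscle, erythroid cells, Schwann cells, dermal papilla and differentiated follicle layers were used only to measure RNA of other cells in each library. Counting the markers whose libraries did not overlap between groups was chosen after the data were seen.

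The genes named in the text followed a rule. For each comparison they were the 8 genes with the highest and the 8 with the lowest log2 fold change among those past the threshold with a mean of at least 10 TPM in the higher group and no overlap between the groups' libraries. Numbered gene models, Rik symbols and haemoglobin genes were left out. Where none passed, up to 5 genes per direction with the smallest p were named as not past the threshold. To these were added up to 4 members of each list past the threshold, or with at least 3 members called, and a fixed set of fasting and stem cell genes whatever their p. Some genes that the rule names are not reported here. The groupings, tests, lists, gene rule and most processing alternatives were set before the data were examined.

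The fold changes at 24 h and 48 h share the 3 ad libitum libraries. Their correlation, covariance and overlap were therefore set beside 100 simulated draws. Each draw simulated every library of the fit, ad libitum ones included, with no change between groups and independent noise for each gene. Both fold changes of a draw shared its ad libitum libraries. Genes called at both times, and fixed lists, were located in the long-term comparison by the percentile of their median among 10000 random lists of the same size matched on mean expression. Scripts were tested on simulated data with 20 draws of 200 changed genes for each comparison. At 4-fold, 69.6% of the changed genes were recovered in the fit of 11533 genes for 24 h against ad libitum, 70.5% for 48 h against ad libitum, 72.0% for 48 h against 24 h, 75.2% of those among 11774 genes for EpiSCs, 61.6% among 12162 for the long-term libraries and 56.0% among 11618 for telogen. At 2-fold, these shares were 11.4%, 14.2%, 14.5%, 19.5%, 11.1% and 6.4%, so a change of 2-fold was mostly not recovered where 200 genes changed. The number of changed genes sets the adjusted threshold. These shares therefore need not hold where many more genes were called, as at 48 h and for EpiSCs. Of the calls in the simulated data, 5.97%, 5.52%, 5.72%, 7.88%, 9.46% and 6.93% were false in the same order, above the nominal 5%.

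The processing alternatives set in advance were a pseudocount of 0.1, a minimum mean of 5 TPM, no filter, quantile normalization, median-ratio scaling between libraries, removal of mitochondrially encoded and ribosomal protein genes with rescaling, limma without the trend or with robust estimation, a fold minimum of 2, an adjusted p under 0.1, other sets of libraries in the fit, the replicate number as a block, and leaving out each library in turn.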

Results

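Polyadenylated RNA was profiled in sorted stem cells of mouse skin to follow how fasting changes gene expression in hair follicle stem cells (HFSCs). The short experiment comprised HFSCs from mice fed ad libitum, fasted for 24 h or fasted for 48 h (3 libraries each) and epidermal stem cells (EpiSCs) from mice fed ad libitum (2 libraries). Further HFSC libraries came from mice kept for 6 months on alternate-day fasting or on food ad libitum (2 each) and from 2nd-telogen follicles (2 libraries). Between 10422 and 12087 genes reached 1 TPM in a library. Within groups, the correlation of log2 values across genes between replicates ran from 0.904 among the 24 h libraries to 0.977 for EpiSCs. The HFSC marker Cd34 averaged 516 ± 146 TPM (SD, n = 3) in ad libitum HFSCs and 0.303 ± 0.274 TPM (SD, n = 2) in EpiSCs.

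Transcripts of the mitochondrial genome took 30.7% ± 4.56 (SD, n = 3) of all TPM in ad libitum HFSCs, 27.5% ± 8.73 after 24 h and 10.02% ± 2.88 after 48 h. The share was 3.22% ± 0.526 in EpiSCs, 3.39% ± 0.721 and 3.88% ± 0.308 in the long-term fasted and fed libraries, and 3.46% ± 0.0531 in telogen (n = 2 each). Because TPM values add up to a fixed total, a lower mitochondrial share goes with higher values of other genes. The median log2 fold change of all genes was 0.42 for 48 h against ad libitum, 0.47 for 48 h against 24 h and 0.50 for EpiSCs against HFSCs. For these comparisons, log2 values after median-ratio scaling, which sets that median near 0, are given beside the deposited ones of named genes.

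**Figure D1:**
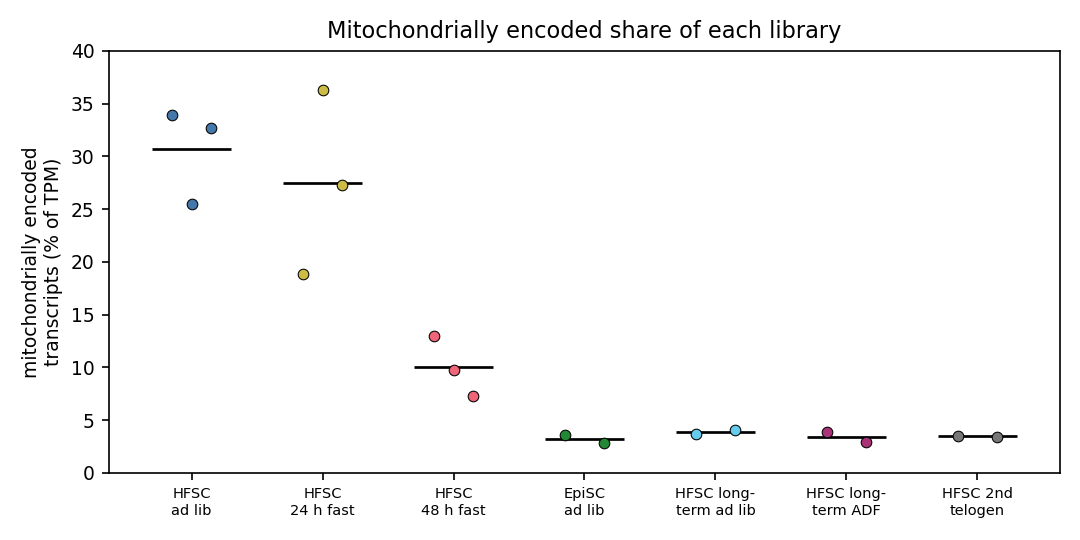
Share of TPM from mitochondrially encoded genes (y axis, percent) in each library of the 7 groups (x axis), with points for libraries and bars for group means. The short-experiment HFSCs of fed mice averaged 30.7% and those fasted for 48 h averaged 10.02%, while each of the 4 groups of EpiSCs, long-term and telogen libraries averaged under 4%.

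After 24 h of fasting, 9 of 22 glucocorticoid response genes, 5 of 17 PPAR targets and 2 of 25 fatty acid oxidation genes rose in HFSCs. The bile acid and steroid sulfate transporter gene Slc10a6 (chromosome 5, 103605711 to 103629403, minus strand, GRCm38/mm10) rose from 0.787 ± 0.687 to 47.7 ± 18.6 TPM (SD, n = 3), a log2 fold change of 4.79 (SE 0.433, adjusted p = 5.97e-05). Pdk4, a kinase that restrains glucose oxidation (chromosome 6, 5483351 to 5496309, minus strand), rose from 0.445 ± 0.683 to 26.2 ± 17.7 TPM (4.15, SE 0.465, adjusted p = 0.000308). Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 42.1 ± 48.9 to 232 ± 50.8 TPM (3.21, SE 0.621, adjusted p = 0.0121). The growth factor gene Ptn (chromosome 6, 36714929 to 36810220, minus strand) fell from 2016 ± 129.5 to 314 ± 47.4 TPM, a log2 fold change of -2.69 (SE 0.32, adjusted p = 0.000443). Cck, which encodes the peptide hormone cholecystokinin, fell from 38.9 ± 26.04 to 0.383 ± 0.664 TPM (-4.76, SE 0.591, adjusted p = 0.00053). Slc10a6, Pdk4, Angptl4, Ptn and Cck each passed the threshold without any single library.

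Of the 22 tested genes of the glucocorticoid response list, 9 rose, 0 fell and 13 were not called at 24 h, and 12 rose and 1 fell when adjusted over the list alone. They included Ddit4, an inhibitor of the growth kinase mTORC1 (6.75 ± 0.853 to 70.2 ± 22.9 TPM), and Klf15, a transcription factor of fasting metabolism (39.7 ± 15.9 to 219 ± 108 TPM, log2 fold change 2.40). Cebpd rose by 2.35, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, from 516 ± 229.8 to 1699 ± 544 TPM (1.76). The receptor gene itself, Nr3c1, was not called (-0.78, SE 0.269, adjusted p = 0.137), nor was Fkbp5, a glucocorticoid-induced co-chaperone (0.89, adjusted p = 0.403). The camera adjusted p of the list was 1.64e-09, and the adjusted p was 0.742 with an estimated correlation. Among 17 PPAR targets of fasting, 5 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.15e-06), and the adjusted p was 0.701 with an estimated correlation. Of 25 fatty acid oxidation genes 2 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 0.000463, and 0.742 with an estimated correlation). Cpt1a, which controls entry of fatty acids into mitochondria, was not called (1.27, SE 0.461, adjusted p = 0.154). Of 27 FOXO and autophagy genes 4 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 3.71e-06, and 0.742 with an estimated correlation), among them Gabarapl1, a protein of the autophagosome (1.73), and the lysosomal protease gene Ctsl (2.20). Immediate early genes, which also respond to tissue dissociation, had 4 of 24 members higher and 0 lower (12 and 0 adjusted over the list alone, adjusted p = 4.73e-07, and 0.742 with an estimated correlation).

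Of the 85 nuclear genes of oxidative phosphorylation 16 fell at 24 h, 0 rose and 69 were not called (40 fell and 1 rose adjusted over the list alone), with a camera adjusted p of 2.98e-12 and an adjusted p of 0.742 with an estimated correlation. Its members included Atp5k, a small subunit of ATP synthase (358 ± 15.8 to 137 ± 39.2 TPM, log2 fold change -1.41, SE 0.231), and Ndufa1 of complex I (-1.36, SE 0.226). The 13 mitochondrially encoded genes had 0 called at this time (median -0.20, adjusted p = 0.256). Phgdh, the first enzyme of serine synthesis, fell from 136 ± 23.8 to 23.8 ± 9.82 TPM (-2.52, SE 0.338, adjusted p = 0.000977), and Odc1, the first enzyme of polyamine synthesis and a MYC target, fell by 2.87 (SE 0.466, adjusted p = 0.00379). Glycolysis (1 rose and 3 fell of 19, adjusted p = 0.0273), cholesterol synthesis (0 and 2 of 24, adjusted p = 0.0354) and ribosome biogenesis (0 and 2 of 25, adjusted p = 0.00962) also passed as lists in the lower direction. Their adjusted p was 0.742, 0.742 and 0.794 with an estimated correlation. Adjusted over the list alone, 1 rose and 6 fell, 0 rose and 2 fell, and 0 rose and 2 fell in these lists. All 3 calls were lost without ad libitum library 1 (0.0647, 0.307 and 0.107), that of glycolysis also without ad libitum library 3 (0.0527), and that of cholesterol synthesis without 24 h library 1 (0.232).

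Genes of stress and cell death changed in part, and stem cell identity genes were not called at 24 h. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), rose from 147 ± 11.7 to 353 ± 81.8 TPM (1.23, SE 0.22, adjusted p = 0.00759). Bbc3, which encodes the pro-apoptotic protein PUMA, rose from 2.72 ± 2.33 to 12.3 ± 3.51 TPM (1.99, SE 0.469, adjusted p = 0.0327). Of the 28 genes of the p53 and apoptosis list 3 rose and 0 fell (4 and 0 adjusted over the list alone), with an adjusted p of 0.0354 and an adjusted p of 0.794 with an estimated correlation. This call was lost without ad libitum library 3 (0.0924) or 24 h library 1 (0.157) or 2 (0.0519). The Bbc3 call was lost without ad libitum library 1 (0.154) or 3 (0.102), 24 h library 1 (0.0822) or 3 (0.0603) or 48 h library 1 (0.0545). Of 21 stem cell identity genes, 0 passed the limma test (0 adjusted over the list alone, camera adjusted p = 0.335), with Cd34 at -0.10 (95% interval -0.76 to 0.56) and Krt15 at -0.69 (-1.30 to -0.07).

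In all, 354 of 11533 genes were called at 24 h, 169 higher and 185 lower, against 1972 at an unadjusted p under 0.05. There were 306 higher and 253 lower after median-ratio scaling, 373 and 331 after quantile normalization, and 227 and 315 without mitochondrial and ribosomal protein genes. With ad libitum library 1, 2 or 3, or 48 h library 2, left out of the fit, the count was 99, 215, 151 or 220. The other lists had few or no called members. Interfollicular epidermis had 1 higher and 2 lower of 19 (mean -0.11, median 0.28, adjusted p = 0.889), and the integrated stress response 2 and 4 of 26 (mean -0.16, median 0.07, 0.943). Antioxidant genes had 2 and 3 of 30 (0.292) and the unfolded protein response 1 and 5 of 21 (0.137), among the lower ones Calr, a chaperone of the endoplasmic reticulum (-1.27, SE 0.215). Matrix and adhesion had 1 and 1 of 21 (0.978), cell cycle 1 and 1 of 31 (0.24) and cAMP response 2 and 0 of 11 (0.378). BMP response had 1 and 0 of 18 (0.256), lipid storage 1 and 0 of 17 (0.256) and epidermal differentiation 0 and 1 of 18 (0.0682). Adjusted over the list alone, these 10 lists held 2 and 4, 5 and 6, 3 and 4, 1 and 6, 4 and 3, 1 and 1, 3 and 1, 1 and 0, 2 and 0, and 0 and 4 called genes. In the lists of fatty acid synthesis (camera adjusted p = 0.492), TCA cycle (0.292), ribosomal proteins (0.57), stress keratinocyte genes (0.998), anti-apoptotic genes (0.699), Wnt and hedgehog (0.492), circadian clock (0.646) and interferon response (0.24), limma called 0 genes over all genes and 0 over each list alone.

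**Figure D2:**
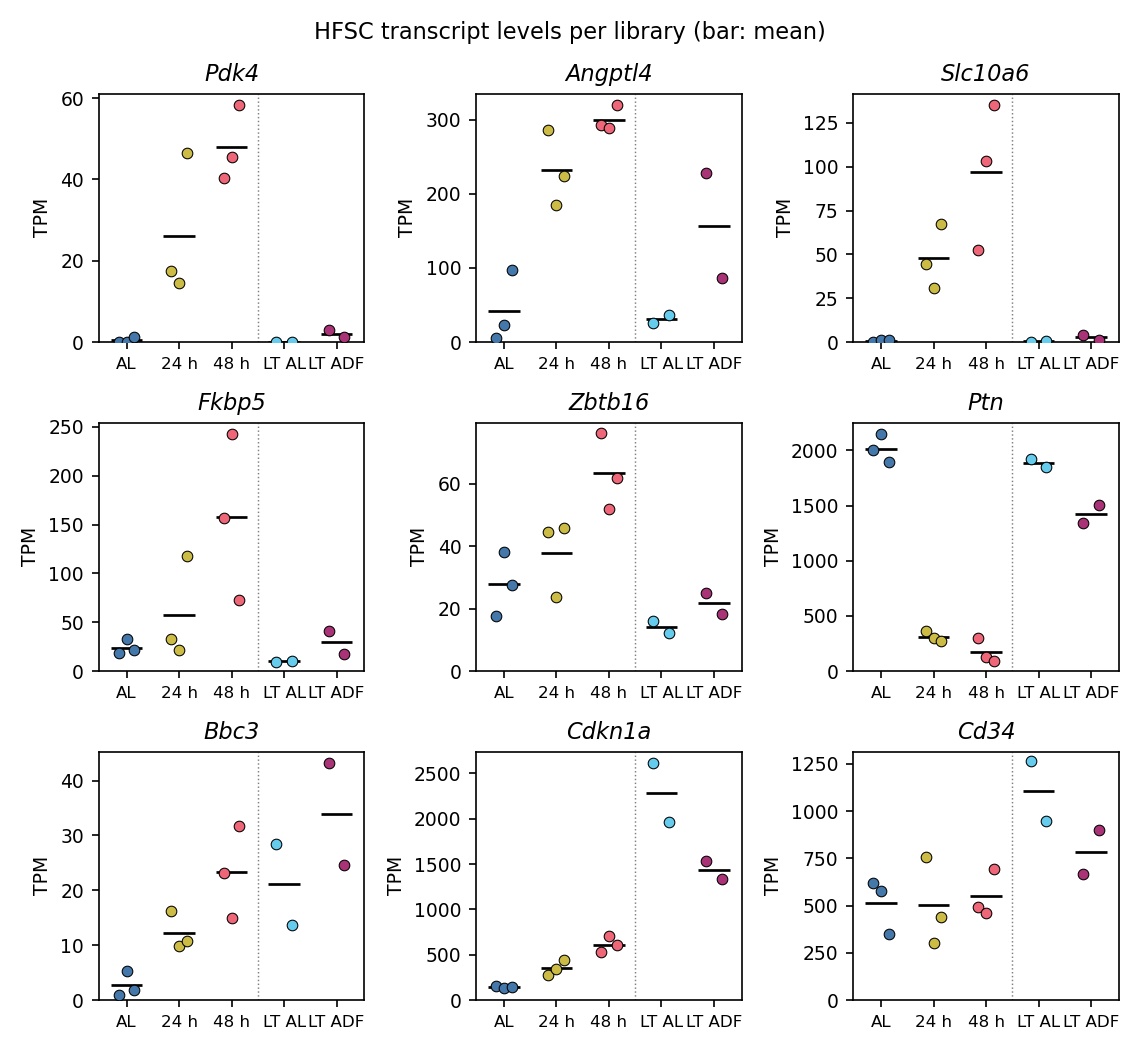
TPM of 9 genes (1 panel each, y axis from 0) in each HFSC library fed ad libitum, fasted for 24 h or 48 h, or kept long-term on food ad libitum or alternate-day fasting (x axis), with points for libraries and bars for means. Pdk4 averaged 0.445, 26.2 and 48.0 TPM and Cd34 516, 501 and 549 TPM in the fed, 24 h and 48 h libraries of the short experiment.

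After 48 h the same fasting genes were again higher than in fed mice. Slc10a6 reached 97.0 ± 41.5 TPM (SD, n = 3), a log2 fold change of 5.76 (SE 0.433, adjusted p = 2.64e-06) and 5.41 after median-ratio scaling. Pdk4 reached 48.0 ± 9.21 TPM (5.17, SE 0.465, adjusted p = 7.97e-06, 4.80 after scaling). Klf15 reached 607 ± 148 TPM (3.95, SE 0.341, adjusted p = 5.82e-06, 3.46 after scaling). Bbc3 rose to 23.3 ± 8.42 TPM (2.83, SE 0.469, adjusted p = 0.0013, 2.42 after scaling). Ptn fell to 175 ± 113 TPM (-3.70, SE 0.32, adjusted p = 5.82e-06, -4.19 after scaling). Gpha2, a glycoprotein hormone subunit, fell from 74.6 ± 16.9 to 6.89 ± 0.668 TPM (-3.24, SE 0.346, adjusted p = 4.21e-05, -3.69 after scaling). These genes passed the threshold under both scalings and without any single library.

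At 48 h, 15 of the 22 glucocorticoid response genes rose and 0 fell (17 and 1 adjusted over the list alone), and 13 rose and 1 fell after median-ratio scaling. Fkbp5 reached 157 ± 84.9 TPM from 24.1 ± 7.69 (2.54, SE 0.514, adjusted p = 0.00452, 2.06 after scaling), and Tsc22d3 2551 ± 378 TPM (2.39, SE 0.305, 1.89 after scaling). FOXO and autophagy genes rose in 16 of 27 and fell in 0 (17 and 0 adjusted over the list alone, 12 and 0 after scaling), with Ctsl at 3.26 (2.76 after scaling) and the mitophagy receptor gene Bnip3 at 2.52 (2.03 after scaling). Of 24 immediate early genes 14 rose and 0 fell (16 and 0 adjusted over the list alone, 10 and 0 after scaling), led by Socs3, a feedback inhibitor of cytokine signalling (3.00, 2.51 after scaling), and Klf6 (2.61, 2.12 after scaling). The camera adjusted p of the 3 lists was 4.07e-08, 1.01e-05 and 1.01e-05, and the adjusted p was 0.566 each with an estimated correlation.

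How many genes of fatty acid use rose at 48 h depended on the scaling. PPAR targets had 12 of 17 members higher and 0 lower (12 and 0 adjusted over the list alone), and 5 and 0 after scaling (camera adjusted p = 0.000147, and 0.566 with an estimated correlation). Fatty acid oxidation had 11 of 25 higher and 0 lower (12 and 0 adjusted over the list alone), and 2 and 0 after scaling (adjusted p = 0.014, and 0.576 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase gene, rose by 1.19 (SE 0.227, 0.70 after scaling), while Hadhb of the trifunctional protein (1.21, SE 0.26) was at 0.71 and no longer called after scaling. Plin2, which coats lipid droplets, and Ucp2 were not called (-0.10 and 0.04, against -0.58 and -0.45 after scaling). BMP response and quiescence genes rose in 6 of 18 and fell in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.014, and 0.566 with an estimated correlation), and 1 and 0 after scaling. The member kept was Cdkn1a, which reached 612 ± 86.9 TPM (2.04, SE 0.22, adjusted p = 4.54e-05, 1.55 after scaling). Of 28 p53 and apoptosis genes 9 rose and 0 fell (11 and 0 adjusted over the list alone), and 4 and 0 after scaling (adjusted p = 0.032, and 0.613 with an estimated correlation). Trp53inp1, a p53-induced protein of autophagy and cell death, rose by 2.93 (SE 0.435, 2.45 after scaling). That list call was lost without ad libitum library 3 (0.0701) or 48 h library 2 (0.0512).

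All 13 mitochondrially encoded genes fell at 48 h under both scalings (13 adjusted over the list alone, camera adjusted p = 1.12e-21, and 0.566 with an estimated correlation). For example, mt-Nd4l fell from 7083 ± 560.2 to 1647 ± 409.6 TPM (-2.13, SE 0.27, -2.62 after scaling). Of 85 nuclear oxidative phosphorylation genes 2 rose and 8 fell (1 and 8 adjusted over the list alone), and 0 rose and 35 fell after scaling (adjusted p = 8.86e-10, and 0.601 with an estimated correlation). Eno1 of glycolysis fell by 1.46 (SE 0.317, adjusted p = 0.00691) and by 1.95 after scaling. Glycolysis had 2 higher and 2 lower of 19 (3 and 4 adjusted over the list alone, 2 and 6 after scaling), and cholesterol synthesis 1 and 0 of 24 (1 and 0 adjusted over the list alone, 1 and 2 after scaling). Both lists passed in the lower direction (adjusted p = 0.0444 and 0.0454, and 0.601 and 0.566 with an estimated correlation) although their means were 0.07 and 0.03 and their medians -0.05 and -0.004. Both calls were lost without ad libitum library 1 (0.0787 and 0.306), 48 h library 1 (0.0803 each) or 2 (0.0758 and 0.0953). That of glycolysis was also lost without ad libitum library 3 (0.0565) or 24 h library 3 (0.051).

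Stem cell identity genes again had few calls at 48 h, with 2 of 21 higher and 1 lower (2 and 3 adjusted over the list alone, 1 and 4 after scaling, camera adjusted p = 0.0835). Cd34 was at 549 ± 127 TPM against 516 ± 146 (0.11, 95% interval -0.55 to 0.77, and -0.39 after scaling), and Lgr5, Sox9, Lhx2 and Krt15 were not called (0.19, 0.41, -0.23 and -0.46, against -0.29, -0.08, -0.72 and -0.96 after scaling). Epidermal differentiation had 1 of 18 higher and 3 lower (1 and 3 adjusted over the list alone, 0 and 3 after scaling), with the homeodomain gene Hopx at -1.35 (SE 0.284, -1.83 after scaling). Cell cycle genes had 3 of 31 higher and 2 lower (3 and 2 adjusted over the list alone, 2 and 2 after scaling), the higher ones including the replication genes Rrm2 (2.68, 2.21 after scaling) and Mcm7 (1.51, 1.03 after scaling). Wnt and hedgehog genes had 1 of 18 higher and 1 lower (1 and 1 adjusted over the list alone, 1 and 3 after scaling). The camera adjusted p of these 3 lists, lower against other genes, was 0.000879, 0.00133 and 0.014, and the adjusted p was 0.566 each with an estimated correlation. The Wnt call was lost without 48 h library 2 (0.0758). Of 18 circadian genes 8 rose and 0 fell (9 and 0 adjusted over the list alone, 4 and 0 after scaling, adjusted p = 0.0697), with the clock repressor gene Nr1d1 at 1.66 (1.17 after scaling).

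The remaining lists at 48 h did not pass camera. Interfollicular epidermis had 7 higher and 4 lower of 19 (2 and 5 after scaling, adjusted p = 0.301), and the integrated stress response 8 and 4 of 26 (5 and 4, 0.837). Antioxidant genes had 6 and 4 of 30 (5 and 6, 0.364) and the unfolded protein response 3 and 1 of 21 (3 and 6, 0.347). Matrix and adhesion had 4 and 2 of 21 (2 and 5, 0.282) and ribosome biogenesis 4 and 1 of 25 (1 and 1, 0.739). Adjusted over the list alone the 6 lists held 8 and 5, 9 and 4, 7 and 4, 3 and 1, 5 and 3, and 4 and 1. Phgdh was again lower (25.9 ± 10.8 TPM, -2.40, SE 0.338, -2.88 after scaling), while the NRF2 gene Nfe2l2 rose by 1.55 (SE 0.305, 1.06 after scaling) and Gstm1, a glutathione transferase, by 2.35 (SE 0.276, 1.86 after scaling). Ribosomal proteins had 5 higher and 0 lower of 76 (0 and 4 after scaling, 0 adjusted over the list alone, 0.265) and TCA cycle 3 and 0 of 22 (1 and 1, 0.947). The cAMP response had 3 and 1 of 11 (2 and 1, 0.503) and lipid storage 3 and 1 of 17 (3 and 1, 0.821), the last with the lipase gene Pnpla2 at 2.40 (1.93 after scaling). The interferon (1 and 1 of 17, 0.122), fatty acid synthesis (1 and 0 of 14, 0.436), anti-apoptotic (1 and 0 of 9, 0.388) and stress keratinocyte lists (1 and 0 of 4, 0.733) had the fewest calls. Adjusted over the list alone, the 7 lists from TCA cycle to stress keratinocyte held 3 and 0, 6 and 1, 3 and 1, 1 and 1, 0 and 0, 0 and 0, and 1 and 0.

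In all, 1765 of 11533 genes were called at 48 h, 1537 higher and 228 lower, or 87.1% higher. Median-ratio scaling, which centres all genes, gave 601 higher and 597 lower (50.2%), and removal of mitochondrial and ribosomal protein genes 675 and 485 (58.2%). Without mitochondrial genes and their nuclear copies, 668 were higher and 571 lower. The count was 748 or 885 without ad libitum library 1 or 3 and 1053, 749 or 744 without 48 h library 1, 2 or 3.

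**Figure D3:**
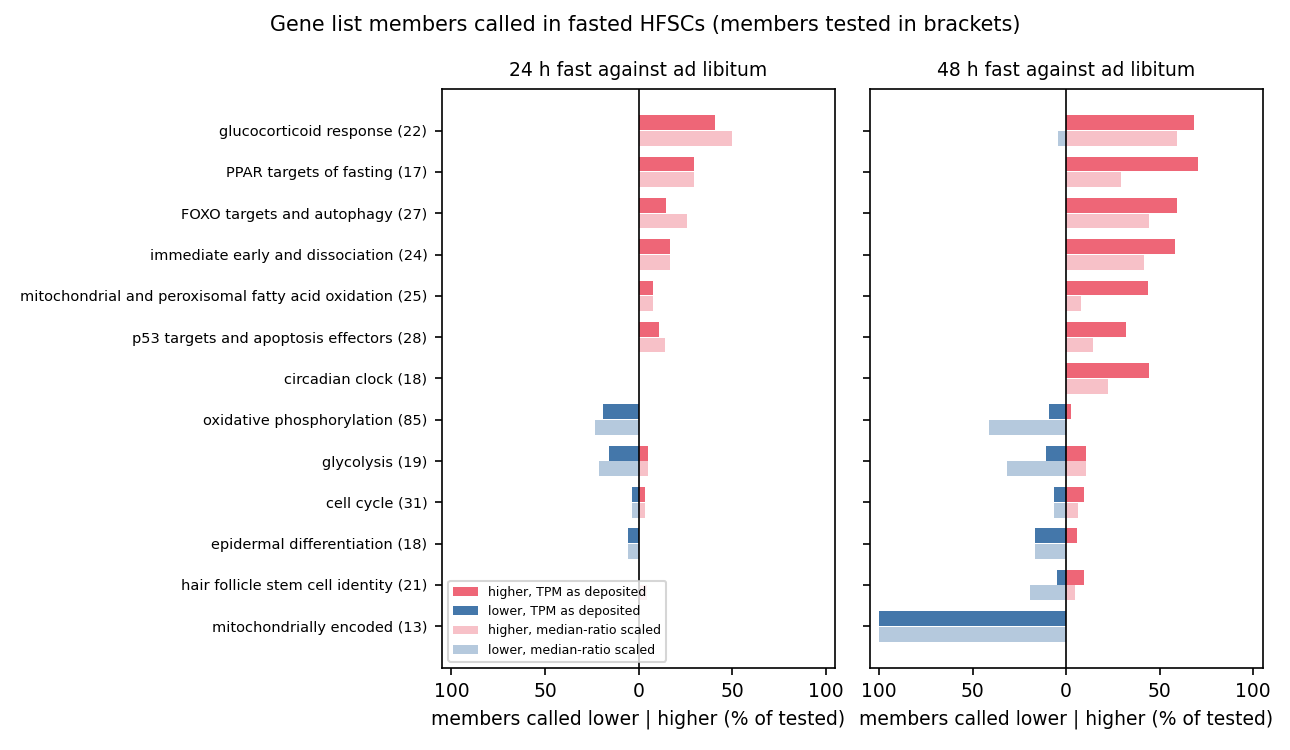
Percent of the tested members of 13 gene lists called higher (right) or lower (left) than in fed HFSCs (x axis) at 24 h and 48 h (panels), with bars for the deposited TPM and for median-ratio scaling. At 48 h glucocorticoid response genes were higher in 15 of 22 members as deposited and 13 after scaling, and mitochondrially encoded genes lower in 13 of 13 under both.

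Set directly against 24 h, the 48 h libraries differed in 5 genes by limma, 3 higher and 2 lower, among 11533 tested and 2461 at an unadjusted p under 0.05. The skin chemokine gene Ccl27a (chromosome 4, 41769467 to 41774247, minus strand) rose from 2177 ± 379.5 to 7613 ± 1816 TPM (1.79, SE 0.243, adjusted p = 0.0215, 1.299 after scaling). Wdr43, of ribosome biogenesis, rose from 16.9 ± 2.39 to 58.5 ± 6.67 TPM (1.73, SE 0.268, 1.26 after scaling), and the histone gene Hist2h2aa1, whose reads near-identical copies could share, by 1.35 (SE 0.222, 0.87 after scaling). The mitochondrial genes mt-Nd4l and mt-Nd4 fell by 1.72 (SE 0.27) and 1.60 (SE 0.261), and by 2.21 and 2.09 after scaling, each of the last 4 genes with an adjusted p of 0.0388. After median-ratio scaling 0 genes were called (872 at an unadjusted p under 0.05), and quantile normalization gave 10. Without 24 h library 3 the count was 345, without 24 h library 1 172 and without 48 h library 3 15. It was 3 without ad libitum library 1, 1 without 48 h library 1, and 0 without each of ad libitum libraries 2 and 3, 24 h library 2 and 48 h library 2. Hence 0 of the 5 calls held without every single library, the adjusted p of Ccl27a reaching 0.108 without 48 h library 2.

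Between 24 h and 48 h the mitochondrially encoded list fell by camera (2 of 13 called, 13 adjusted over the list alone, adjusted p = 6.14e-43, and 0.129 with an estimated correlation). Ribosome biogenesis (1 higher, 0 lower of 25, 5 and 0 adjusted over the list alone, adjusted p = 0.0101) and circadian genes (0 of 18, 3 and 0 adjusted over the list alone, adjusted p = 0.031) passed in the higher direction, and the adjusted p was 0.991 each with an estimated correlation. Ribosomal proteins, cell cycle, Wnt and hedgehog (adjusted p = 0.0101 each) and differentiation (0.0271) passed in the lower direction with 0 genes called by limma over all genes or over each list alone. Their means were positive (0.16, 0.08, 0.12 and 0.24) and below the median of all genes, and the adjusted p was 0.991, 0.979, 0.979 and 0.991 with an estimated correlation. The circadian call was lost without 24 h library 1 (0.282), 48 h library 1 (0.0708) or 3 (0.057), that of ribosomal proteins without 24 h library 1 (0.45) or 48 h library 2 (0.0969), and that of the cell cycle without 24 h library 2 (0.32). The Wnt call was lost without 48 h library 2 (0.129), and that of differentiation without 24 h library 2 (0.655) or 3 (0.577) or 48 h library 1 (0.285) or 2 (0.101).

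The changes at both times went together across genes, which are not independent replicates. The correlation of the log2 fold changes was 0.732 (rho 0.725) over 11533 genes. Simulated unchanged groups that shared simulated fed libraries gave 0.499 (0.479 to 0.521). The covariance was 0.393 against a simulated 0.098, and 68.7% of genes had the same sign against 66.7%. Of the called genes 166 were higher at both times, where independent lists would share 22.5 and simulated unchanged groups 0.02. A further 91 were lower at both, where these values were 3.66 and 0.01, and 0 of those called at both went in opposite directions. With no change simulated, few genes can be called at either time, so the simulated overlap is near 0 by design. It cannot show how many shared calls the common fed libraries add. The simulated noise was independent between genes, so the simulated values leave out deviations that many genes of a library share. Part of the excess may come from the shared controls, since 3 libraries cannot be split.

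To place the HFSCs within the skin epithelium, EpiSCs and HFSCs of fed mice were compared. Of 21 stem cell identity genes 17 were lower in EpiSCs, 1 was higher and 3 were not called. Cd34, which encodes a surface glycoprotein of bulge cells (chromosome 1, 194938819 to 194961279, plus strand), was far lower (log2 fold change -8.61, SE 0.3, adjusted p = 1.67e-06, -8.89 after scaling). Angptl7, a secreted angiopoietin-like factor (chromosome 4, 148495183 to 148500460, minus strand), averaged 1933 ± 982 TPM (SD, n = 3) in HFSCs and 0.0557 ± 0.0248 TPM (n = 2) in EpiSCs (-10.70, SE 0.395, adjusted p = 1.97e-06, -10.93 after scaling). The transcription factor genes Lhx2 (-6.17, SE 0.359) and Sox9 (-3.65, SE 0.251) were lower as well (-6.40 and -4.14 after scaling). Lgr5, Grem1, Tbx1 and Shisa2 were listed at 0 in both EpiSC libraries and between 32.0 and 277 TPM in the HFSC libraries. Ly6a, which encodes the surface antigen Sca-1 (chromosome 15, 74994877 to 74998031, minus strand), was higher in EpiSCs, at 644 ± 35.1 against 3.52 ± 0.2996 TPM (7.16, SE 0.226, adjusted p = 1.39e-06, 6.67 after scaling). Which of these genes also served in the sort is not given in the sources used here, and such a gene would be no finding.

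The stem cell identity list had 17 lower and 1 higher (18 and 1 adjusted over the list alone, 19 and 1 after scaling), with a camera adjusted p of 7.37e-18 and an adjusted p of 0.662 with an estimated correlation. The higher member was Itga6, a subunit of the hemidesmosome integrin (326 ± 49.2 against 27.6 ± 2.48 TPM, 3.51, 2.98 after scaling). Krt15, a basal keratin often used to mark the bulge, was not called, at 34153 ± 410.1 against 38033 ± 1439 TPM (-0.16, SE 0.106, adjusted p = 0.271, -0.69 after scaling). Nfatc1, a regulator of bulge quiescence, was lower by limma (-1.72, SE 0.359, adjusted p = 0.00651, -2.23 after scaling), a call lost without EpiSC library 1 (0.12). Interfollicular epidermis genes went both ways, 13 higher and 6 lower of 19 (13 and 6 adjusted over the list alone, 11 and 6 after scaling, adjusted p = 0.483), and so did differentiation genes, 11 and 6 of 22 (11 and 8 adjusted over the list alone, 9 and 7 after scaling, 0.793). Krt1 and Krt10, keratins of the suprabasal layers, were higher in EpiSCs at 805 ± 158 and 1338 ± 158 TPM against 18.8 ± 7.42 and 149 ± 34.8 TPM (5.41 and 3.17, 4.88 and 2.64 after scaling), while Ivl was not called (-1.25, adjusted p = 0.0751) and was called lower after scaling (-1.65, adjusted p = 0.0441).

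Cell cycle genes were higher in EpiSCs in 29 of 39 members and lower in 0 (34 and 0 adjusted over the list alone, 18 and 0 after scaling), including the replication licensing genes Mcm2 (2.88, 2.37 after scaling) and Mcm3 (2.78, 2.28 after scaling). Of 19 interferon response genes 13 were higher and 0 lower (13 and 0 adjusted over the list alone, 11 and 0 after scaling), with the MHC class I gene H2-K1 at 2489.7 ± 230.3 against 217 ± 3.31 TPM (3.51, 2.98 after scaling) and B2m at 2.503 (1.97 after scaling). Ribosome biogenesis genes were higher in 21 of 25 and lower in 0 (21 and 0 adjusted over the list alone, 9 and 0 after scaling). The camera adjusted p of these lists was 1.89e-05, 0.00142 and 0.00219, and the adjusted p was 0.771, 0.662 and 0.771 with an estimated correlation. Fatty acid oxidation had 13 of 25 higher and 0 lower (14 and 0 adjusted over the list alone, 5 and 1 after scaling, adjusted p = 0.0475), and ribosomal proteins 55 of 76 and 0 (57 and 0 adjusted over the list alone, 2 and 0 after scaling, adjusted p = 0.01). The adjusted p of both was 0.771 and 0.858 with an estimated correlation. The ribosomal call was lost without EpiSC library 1 (0.203), and that of fatty acid oxidation without EpiSC library 1 (0.0533) or 2 (0.0549) or HFSC library 1 (0.0521).

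Immediate early genes were higher in EpiSCs in 21 of 24 members and lower in 1 (22 and 1 adjusted over the list alone, 16 and 2 after scaling), with Atf3 at 4512 ± 713 against 487 ± 129 TPM (3.23, 2.70 after scaling). The cAMP response had 11 of 13 higher and 0 lower (11 and 1 adjusted over the list alone, 8 and 1 after scaling). Both lists passed camera (adjusted p = 0.000241 and 0.0443, and 0.771 each with an estimated correlation), and the cAMP call was lost without HFSC library 2 (0.0857). In the same libraries all 13 mitochondrially encoded genes were lower in EpiSCs under both scalings (13 adjusted over the list alone, adjusted p = 1.67e-16, and 0.662 with an estimated correlation), for example mt-Co1 (-3.35, -3.89 after scaling). The receptor gene Nr3c1 was lower (-1.47, SE 0.223, adjusted p = 0.00151, -1.999 after scaling). Cpt1a was called higher (1.87, adjusted p = 0.0303), and this was lost after scaling (1.38) and without HFSC library 1 (0.0784) or 3 (0.105) or EpiSC library 1 (0.197) or 2 (0.22).

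Antioxidant genes differed in both directions, with 13 higher and 7 lower of 29 (14 and 7 adjusted over the list alone, 8 and 8 after scaling, adjusted p = 0.634). Sod2, the mitochondrial superoxide dismutase, was higher in EpiSCs at 147 ± 8.48 against 50.8 ± 5.85 TPM (1.52, SE 0.191, 0.99 after scaling). Sod1, the cytosolic enzyme, was lower at 226 ± 9.42 against 739 ± 57.2 TPM (-1.70, SE 0.139, -2.23 after scaling), as were the quinone reductase gene Nqo1 (-2.55, SE 0.29, -3.05 after scaling) and Gpx2 (-2.68, SE 0.398, -2.88 after scaling). Gpx1 was called higher (0.47, SE 0.121, adjusted p = 0.0154) but stood at -0.06 and was not called after scaling, nor without EpiSC library 1 (0.139) or 2 (0.0642). Catalase (Cat) and Hmox1 were not called (0.12, adjusted p = 0.702, and 1.09, adjusted p = 0.0556, against -0.40 and 0.63 after scaling).

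Developmental signalling lists also went both ways. Wnt and hedgehog genes were higher in 7 and lower in 8 of 19 (7 and 8 adjusted over the list alone, 6 and 8 after scaling, mean 0.09, median -0.33, adjusted p = 0.0749), with the ligand genes Wnt3 (4.93, 4.48 after scaling) and Wnt4 (4.95, 4.49 after scaling) higher in EpiSCs. BMP response genes were higher in 7 and lower in 9 of 19 (7 and 9 adjusted over the list alone, 5 and 10 after scaling, mean 0.04, median -0.57, adjusted p = 0.0507), with Bmp4 at 5.32 (4.95 after scaling) and Id2, a BMP target, at -4.73 (-5.25 after scaling). Of the 16 other lists, which camera did not call (adjusted p 0.0749 to 0.991), oxidative phosphorylation had 45 higher and 2 lower of 85 (3 and 5 after scaling, adjusted p = 0.116) and glycolysis 14 and 3 of 20 (7 and 4, 0.223). The p53 list had 15 and 2 of 28 (8 and 3, 0.118), integrated stress response 15 and 0 of 26 (9 and 2, 0.0813), unfolded protein response 12 and 0 of 21 (4 and 1, 0.0813) and TCA cycle 10 and 0 of 22 (2 and 2, 0.223). Adjusted over the list alone these 6 lists held 47 and 2, 15 and 3, 15 and 2, 16 and 2, 13 and 0, and 15 and 0.

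In all, 4782 of 11774 genes were called between EpiSCs and HFSCs, 3711 higher and 1071 lower in EpiSCs (77.6% higher). Median-ratio scaling gave 1983 and 1835 (51.9% higher), and removal of mitochondrial and ribosomal protein genes 1993 and 1698 (54.0%). Without mitochondrial genes and their nuclear copies, 1804 were higher and 1904 lower. Without EpiSC library 1 or 2 the count was 1253 or 1367. Of 35 markers of other cells with a mean of at least 1 TPM, 9 were higher in both EpiSC libraries than in every HFSC library. A further 15 were lower, where chance gives 10% each way if no gene differs. The share over all genes was not counted, and with 4782 of 11774 genes called it may also exceed 10%. The lower ones included 5 of 5 fibroblast markers past this minimum, such as Sparc (129 against 1031 TPM on average). They also included 3 of 3 melanocyte markers past it, such as Mitf (1.45 against 26.9 TPM). Other markers of these cells were near the floor in fed HFSCs, at most 0.04 TPM for Col3a1, 0.0104 for Pdgfra, 0.369 for Sox10 and 0.306 for Kit. The counts therefore do not show that the HFSC libraries held fibroblast or melanocyte RNA. The antigen presentation genes Cd74 (14.9 against 6.12 TPM) and H2-Eb1 (5.15 against 1.10 TPM) were among the higher ones.

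**Figure D4:**
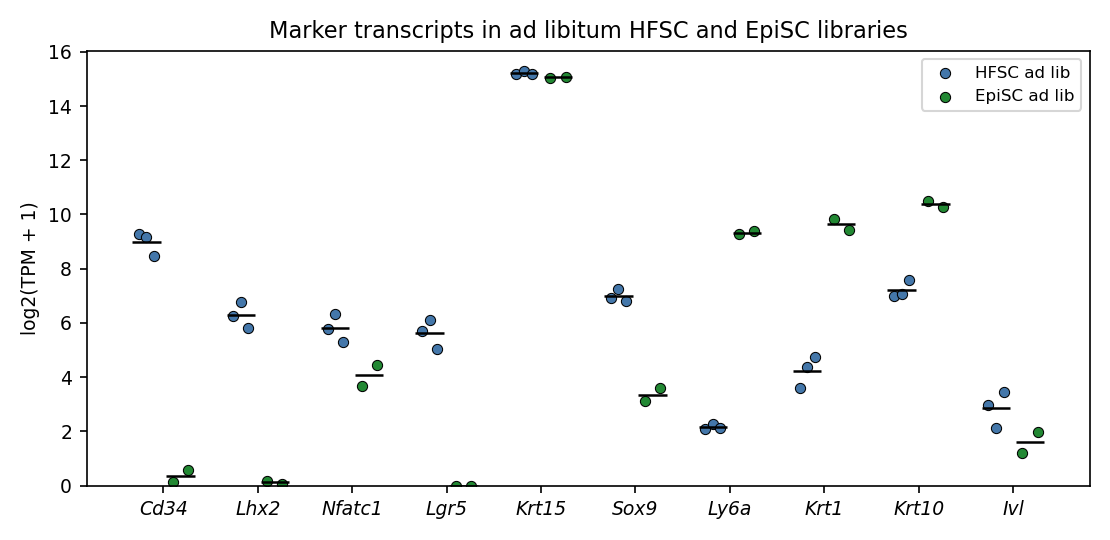
Values of 10 marker genes, log2(TPM + 1) on the y axis, in each HFSC and EpiSC library of fed mice, with points for libraries and bars for means. Cd34 averaged 516 TPM in HFSCs and 0.303 in EpiSCs, and Ly6a 3.52 and 644 TPM.

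The long-term comparison asked what 6 months of alternate-day fasting leaves in HFSCs on the day after a fast. Cell cycle genes had higher values in the fasted libraries, although no single one passed the threshold: Ccnb1, the mitotic cyclin B1 gene (chromosome 13, 100778650 to 100786570, minus strand), was at 55.6 ± 12.7 against 8.02 ± 0.330 TPM (SD, n = 2), a log2 fold change of 2.63 (SE 0.301, adjusted p = 0.14). Cdk1, its kinase partner, was at 2.44 (SE 0.31, adjusted p = 0.169) and Cdc20, which drives exit from mitosis, at 2.25 (SE 0.244, adjusted p = 0.14). Of 41 cell cycle genes 0 were called by limma over all genes and 25 higher and 0 lower adjusted over the list alone. The list passed camera (median 1.60, adjusted p = 1.07e-18), with an adjusted p of 0.26 with an estimated correlation and 0.0561 by fry. Some markers of other cells also separated these libraries. Of 50 such markers with a mean of at least 1 TPM, 14 were higher in both fasted libraries than in both fed ones and 7 were lower. If no gene differs, chance gives 16.7% each way. The share over all genes was not counted, so these counts do not show a difference in cell composition. The melanocyte gene Pmel was at 21.3 and 4.73 against 0.541 and 0.292 TPM, Tyrp1 at 13.7 and 4.52 against 2.91 and 1.35 TPM, and the endothelial gene Egfl7 at 15.7 and 16.8 against 4.33 and 7.88 TPM. Of 9 markers of the inner bulge and hair lineage 2 were higher, the hair keratin gene Krt35 at 14.1 and 0.963 against 0 and 0.0225 TPM and Krt75 at 3.33 and 4.88 against 0.621 and 2.45 TPM. Krt71 and Krt25, keratins of the inner root sheath, were at 15.5 and 5.26 TPM in fasted library 1 and at most 4.92 and 2.39 TPM in the other 3 libraries. The antigen presentation gene Cd74 was lower, at 85.6 and 50.5 against 108 and 153 TPM. The melanocyte gene Dct overlapped, at 48.3 and 12.04 against 26.3 and 11.9 TPM, as did the sebocyte gene Far2, at 1.86 and 31.5 against 3.04 and 25.5 TPM.

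Epidermal differentiation genes had lower values after long-term fasting, with 0 of 22 called over all genes and 7 lower and 0 higher adjusted over the list alone (median -1.25, adjusted p = 3.79e-07, and 0.778 with an estimated correlation). Cnfn, of the cornified envelope, was at 43.3 ± 34.7 against 195 ± 77.5 TPM (-2.35, SE 0.573, adjusted p = 0.258), and Spink5, a protease inhibitor of the outer epidermis, at -2.07 (SE 0.512, adjusted p = 0.258). PPAR targets passed in the higher direction (0 of 18 called, 6 and 0 adjusted over the list alone, adjusted p = 0.0389), stress keratinocyte genes in the lower (0 of 8, 0 and 2, 0.0389) and ribosomal proteins in the higher (0 of 76, 0 and 0, 0.00308). Their adjusted p was 0.778, 0.778 and 0.815 with an estimated correlation. The PPAR call was lost without fasted library 1 (0.0541) or fed library 2 (0.46), that of stress keratinocyte genes without fasted library 2 (0.419) or fed library 1 (0.0913) or 2 (0.435), and that of ribosomal proteins without fed library 1 (0.63). Angptl4 was at 2.16 on the log2 scale (SE 0.451, adjusted p = 0.244) and Cpt1a at 1.75 (SE 0.33, adjusted p = 0.223). The values of Cd34 and Cdkn1a were -0.50 (SE 0.257) and -0.66 (SE 0.248), and those of Fkbp5 and Tsc22d3 1.364 (SE 0.438) and 1.358 (SE 0.246), none past the threshold.

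Of 12162 genes limma called 1 over the long-term comparison, and 284 (190 higher and 94 lower) with the replicate number as a block. The former was the ribosomal protein pseudogene Rpl31-ps8, at 0 TPM in both fed libraries and 250 and 133 TPM in the fasted ones. Its reads could be shared by copies of the gene. Its call was lost without fed library 2 (0.0556). At an unadjusted p under 0.05 there were 1720 genes, and without fasted library 1 or 2 or fed library 1 or 2 limma called 14, 3, 16 or 0. In the remaining 25 lists camera gave adjusted p between 0.0528 and 0.749 and limma called 0 members over all genes. Adjusted over the list alone, matrix and adhesion had 5 higher and 0 lower of 21, circadian genes 4 and 1 of 18 and fatty acid oxidation 2 and 0 of 25. The cAMP response had 1 and 1 of 13, the integrated stress and glucocorticoid responses 1 and 0 of 26 and of 21, mitochondrially encoded genes 0 and 1 of 13, and the others 0.

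**Figure D5:**
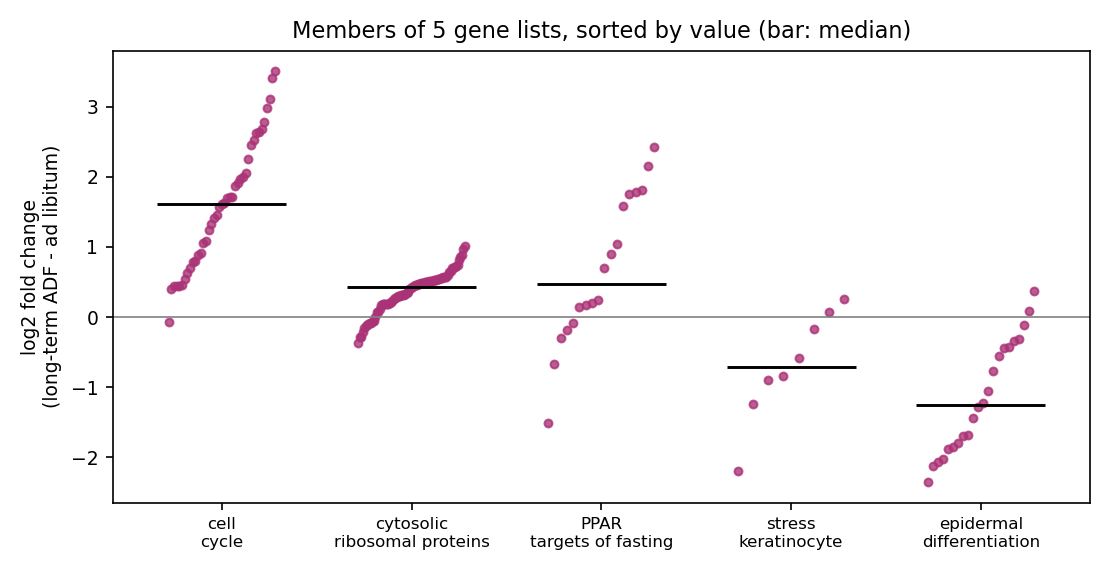
Log2 fold changes of the tested members of 5 gene lists (y axis) in HFSCs after 6 months of alternate-day fasting against food ad libitum, with points for genes and bars for list medians. The median was 1.60 for 41 cell cycle genes and -1.25 for 22 differentiation genes, with 0 genes of either list past the threshold over all genes.

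Genes called higher at both 24 h and 48 h had a median long-term log2 fold change of 0.27 (161 genes, 100 above 0 and 61 below), above 100% of 10000 expression-matched random lists, whose median was 0.06. For the 88 genes called lower at both times the median was 0.16, at percentile 92.2 of its random lists. The 16 PPAR targets tested in both experiments had a median of 0.80 (percentile 100), and 21 glucocorticoid genes one of 0.42 (percentile 99.4). The medians of 31 cell cycle genes were -0.29 at 24 h and -0.36 at 48 h and 1.60 long-term (percentile 100), and those of 18 differentiation genes -0.47, -0.22 and -1.17 (percentile 0). Random lists leave out the correlation between genes, and with an estimated correlation the long-term adjusted p was 0.778 for PPAR targets and 0.815 for glucocorticoid genes, which camera did not call at the preset correlation either (adjusted p = 0.415). Over 11131 genes the long-term changes correlated with those at 24 h at 0.074 and with those at 48 h at 0.003, across genes, which are not independent replicates. The experiments share no library, and these values describe where the lists lay and test no difference between the experiments.

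Second-telogen HFSCs were set against fed HFSCs 2 and 3, the other columns of their table. The names of those fed columns carry an unexplained prefix, ana1, and the labels give no hair cycle stage for them, so which stage telogen was compared with is not known here. Telogen libraries held far more of several stress and growth factor transcripts. Cebpb, a transcription factor of the acute response (chromosome 2, 167688915 to 167690418, plus strand), was at 843 ± 106 against 2.83 ± 1.22 TPM (SD, n = 2), a log2 fold change of 7.82 (SE 0.38, adjusted p = 6.75e-14). Fosl1, a subunit of AP-1 (chromosome 19, 5447547 to 5455946, plus strand), was at 579 ± 135 against 5.48 ± 1.70 TPM (6.49, SE 0.376, adjusted p = 2.6e-12), and the growth factor gene Hbegf at 4.92 (SE 0.369, adjusted p = 5e-10). Cdkn1a was at 1599 ± 135 against 141 ± 5.44 TPM (3.49, SE 0.285) and Atf3 at 3.01 (SE 0.279). These 5 genes kept their call without any single library. Of 24 immediate early genes 20 were higher and 0 lower (21 and 0 adjusted over the list alone, 15 and 0 after scaling), and of 12 cAMP response genes 7 and 0 (9 and 0 adjusted over the list alone, 7 and 0 after scaling). The camera adjusted p was 2.78e-17 and 7.48e-08, and the adjusted p was 0.65 and 0.734 with an estimated correlation.

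All 13 mitochondrially encoded genes were lower in telogen libraries and 11 after scaling (13 adjusted over the list alone, adjusted p = 1.32e-20, and 0.65 with an estimated correlation), with mt-Atp6 at -3.45 (SE 0.307). BMP response and quiescence genes were higher in 7 of 18 and lower in 0 (8 and 0 adjusted over the list alone, 6 and 0 after scaling), among them Fgf18, a quiescence signal of the bulge (58.4 ± 17.8 against 3.85 ± 1.46 TPM, 3.62), whose call was lost without either telogen library (0.129 and 0.0763). Stress keratinocyte genes were higher in 3 of 5 (3 and 0 adjusted over the list alone), interferon genes in 6 of 18 (7 and 0) and antioxidant genes in 6 of 30 (12 and 0), and lower in 0. In the same libraries 7 of 8 immune markers with a mean of at least 1 TPM were higher in both telogen libraries than in both fed ones. None was lower, where chance gives 16.7% each way if no gene differs. The share over all genes was not counted for telogen. Of 6 fibroblast markers 3 were higher and 2 lower, 3 of 3 erythroid markers were higher, and over all cell types 17 of 36 were higher and 6 lower. Cd74 was at 34.3 and 33.7 against 6.23 and 3.93 TPM, H2-Ab1 at 23.2 and 18.4 against 4.74 and 9.198 TPM, Lyz2 at 4.74 and 5.14 against 0.0624 and 0 TPM, and the fibroblast gene Dcn at 17.2 and 22.8 against 1.25 and 5.62 TPM. The camera adjusted p of the BMP, stress keratinocyte, interferon and antioxidant lists was 7.48e-08, 6.22e-05, 0.000168 and 0.00146, and the adjusted p was 0.65 each with an estimated correlation. Ribosomal proteins had 19 of 76 higher and 0 lower (36 and 0 adjusted over the list alone, 1 and 0 after scaling, adjusted p = 7.15e-08, and 0.879 with an estimated correlation), a call lost without the telogen column numbered 3 (0.0668). Interfollicular epidermis had 7 of 19 higher and 0 lower (7 and 2 adjusted over the list alone, adjusted p = 0.011, and 0.879 with an estimated correlation). Stem cell identity genes had 2 of 22 higher and 0 lower (6 and 1 adjusted over the list alone, adjusted p = 0.00701, and 0.879 with an estimated correlation), a call lost without fed library 3 (0.0567) or the telogen column numbered 2 (0.0859).

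A further 7 lists passed camera in telogen, and each call depended on single libraries and was lost with an estimated correlation, with an adjusted p of 0.734 for differentiation and 0.879 for the other 6. Differentiation had 1 of 18 higher and 4 lower (3 and 6 adjusted over the list alone, adjusted p = 0.00701), lost without fed library 3 (0.499) or telogen column 2 (0.187). Oxidative phosphorylation had 4 of 85 higher and 0 lower (4 and 0, 0.000751), lost without fed library 2 (0.148) or telogen column 3 (0.571). The glucocorticoid response had 7 higher and 2 lower of 22 (9 and 2, 0.0494), lost without fed library 3 (0.108) or column 3 (0.271), and FOXO and autophagy 6 and 0 of 27 (8 and 1, 0.0302), lost without fed library 2 (0.0858) or column 2 (0.13). The integrated stress response had 5 and 0 of 26 (5 and 0, 0.024), lost without fed library 3 (0.112) or column 3 (0.129). Ribosome biogenesis had 2 and 0 of 25 (2 and 0, 0.0226), lost without fed library 3 (0.353) or column 2 (0.0661), and cholesterol synthesis 1 and 0 of 24 (2 and 0, 0.0153), lost without column 2 (0.258).

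In all, 709 of 11618 genes were called in telogen, 582 higher and 127 lower (82.1% higher). Median-ratio scaling gave 640 and 213 (75.0%), and removal of mitochondrial and ribosomal protein genes 338 and 223 (60.2%). Without mitochondrial genes and their nuclear copies, 309 were higher and 302 lower. Without a telogen library the count was 29 or 77, and without fed library 3 it was 352.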

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

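The tests of mitochondrial share, rescaling and pseudogenes in this part were chosen after the results were seen, and the counts of other splits were set before. Among the genes of both fasting times, 5 stood out because the 48 h and 24 h effects differed by the limma test of the difference itself. These were Ccl27a (log2 difference 1.79, SE 0.243, adjusted p = 0.0215), Wdr43 (1.73, SE 0.268), Hist2h2aa1 (1.355, SE 0.222), mt-Nd4 (-1.60, SE 0.261) and mt-Nd4l (-1.72, SE 0.27). Each was lost without 48 h library 2, with an adjusted p of 0.108, 0.171, 0.27, 0.266 and 0.266. The 22 fixed genes and 30 lists were also checked for opposite directions, which Cdkn1a, Lhx2 and the glycolysis list showed. For these, every 24 h library lay on one side of the fed libraries of its table. Both long-term fasted libraries lay on the other side of theirs. With 2 long-term libraries per group some such cases can arise by chance. The log2 values for Cdkn1a were -0.66 (SE 0.248) long-term, 1.23 (SE 0.22) at 24 h and 2.04 (SE 0.22) at 48 h, a difference that was not tested. Lhx2 was at 0.92 (SE 0.336) long-term, -0.96 (SE 0.316) at 24 h and -0.23 (SE 0.316) at 48 h, and this difference was not tested either. The mean over all 20 members of the glycolysis list, including those under the minimum of 1 TPM, was 0.31 long-term, -0.31 at 24 h and 0.08 at 48 h, again not tested.

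For each short fasting comparison the 6 libraries form 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many calls. The real split gave 354, 1765 and 5 genes for 24 h and 48 h against ad libitum and for 48 h against 24 h, and the highest other split gave 1, 1 and 2.

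The share of mitochondrially encoded transcripts was lower in every 48 h library than in every fed library. One short transcript, mt-Atp8, does not set this, since without it the lowest fed library still lay 8.23 percentage points above the highest 48 h library. Poorer RNA in the fed libraries would give fewer detected genes, and these had 241 more on average (11816 ± 359 against 11575 ± 46.7) once mitochondrial genes were removed, but within their spread, so this stays open. Handling that lowers the share and also induces immediate early genes would give a negative correlation within groups. The share and the mean immediate early value correlated positively, at r = 0.442 over 9 libraries (exact permutation p = 0.528, rho 0.567, exact p = 0.259) and 0.192 without the 2 farthest, which gives no support to it and too little to exclude it. A lower mitochondrial RNA content after 48 h of fasting, which the design names, cannot be told apart from these explanations, because too few libraries decide.

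Most genes called at 48 h were higher, 1537 of 1765. A candidate explanation is rescaling by the lower mitochondrial share. The median log2 change of nuclear genes, 0.43, differed by -0.003 from the value computed from the shares of mitochondrial genes and their nuclear copies. Median-ratio scaling centres all genes and so cannot test this explanation. Removal of mitochondrially encoded and ribosomal protein genes, which sets no median, left 675 genes higher and 485 lower, so part of the imbalance stayed. Removal of mitochondrial genes with their nuclear copies left 668 higher and 571 lower, a more even split. For EpiSCs the median was 0.51 and the computed value 0.56, while for telogen they were 0.03 and 0.51. Whether total nuclear RNA per cell changed was not tested.

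Telogen libraries differed from fed HFSCs in 709 genes, of which 582 were higher. Numbered, Rik and pseudogene symbols made up 56 of the 582, and 634 genes were called higher without them. Such symbols are therefore few among the higher genes. Their removal leaves the values of all other genes unchanged, so it cannot tell whether reads shared between pseudogene copies raised those. Among the lower genes such symbols made up 45 of 127, against 707 of 11618 genes tested, and 115 were called lower without them. Whether shared reads account for the lower genes stays open too. A batch or processing difference of the telogen libraries was not tested. It cannot be told apart from hair cycle stage, because the submitters' processing notes name another read trimmer for the telogen libraries than for the fed ones.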

How the results depend on the processing

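Removal of mitochondrial genes with their nuclear copies, the telogen count without pseudogene symbols, and the correlation without single libraries were chosen after the data were seen. The other alternatives were set in advance, and the cause of each change below was not tested. Of 62 list results past the threshold, camera with an estimated correlation called 0. Fry kept 19, lost 37 and reversed 6, whose means were 0.084 (cell cycle), 0.162 (ribosomal proteins), 0.235 (differentiation) and 0.125 (Wnt and hedgehog) for 48 h against 24 h, and 0.027 (cholesterol synthesis) and 0.074 (glycolysis) for 48 h against ad libitum. Those kept were 9 for EpiSCs, 8 at 48 h and 1 at 24 h against ad libitum, and 1 for 48 h against 24 h. Fry lost 9 lists at 24 h, all 17 of telogen and all 5 long-term. Median-ratio scaling kept 54 of the 62, a pseudocount of 0.1 kept 56 and a minimum of 5 TPM kept 50. Of 391 calls of named genes median-ratio scaling kept 340, ended 50 and reversed Gpx1 in EpiSCs (-0.061), which was then not called. It called 9 of 136 named genes not called before. Named genes were chosen in part for large changes, so this share need not hold for all calls. Of all genes called, this scaling called 827 of 1765 the same way at 48 h and 3051 of 4782 for EpiSCs. At 24 h it kept 347 of 354, for telogen 615 of 709 and long-term 1 of 1. For 48 h against 24 h it kept 0 of 5.

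At 24 h (354 genes) the count was 627 at an adjusted p under 0.1, 121 without the trend, 559 with median-ratio scaling, 704 with quantile normalization, 542 without mitochondrial and ribosomal protein genes, 609 without mitochondrial genes and nuclear copies, 61 with no filter and 179 with only the libraries compared. At 48 h (1765) it was 2688 at 0.1, 1160 without mitochondrial and ribosomal protein genes, 918 with no filter and 2880 with only the libraries compared. For 48 h against 24 h (5) it was 51 at 0.1, 11 with all 11 libraries of the short experiment, 22 with robust estimation, 31 at a minimum of 5 TPM, 2 with only the libraries compared, 1 with a pseudocount of 0.1 and 10 with quantile normalization. It was 0 without the trend, with median-ratio scaling, with no filter and with either removal of mitochondrial genes. The long-term count (1) was 0 without the trend and with no filter, and the telogen count (709) was 369 without the trend and 4 with no filter. For EpiSCs (4782) each alternative that kept every library gave a count within 1.5 times. Similar counts do not mean the same genes, since median-ratio scaling called 3051 of the 4782 the same way.

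Leaving out each library in turn gave 99 to 489 genes at 24 h, 744 to 2448 at 48 h, 0 to 345 for 48 h against 24 h, 1253 to 5610 for EpiSCs, 0 to 16 long-term and 29 to 553 for telogen, where an arm left with 1 library was assumed to vary like the others. The correlation of both fasting times (0.732) ran from 0.621 to 0.774. The mean of the ribosomal protein genes relative to all genes, for 48 h against 24 h, ran from -0.446 to -0.116, and the camera direction turned at the latter, without 24 h library 1. Lists kept their call in 355 of 412 such fits.

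Same-numbered libraries did not deviate together (r -0.132 to 0.048 in the 9 short pairs, -0.004 long-term and 0.02 to 0.05 for EpiSCs). Short pairs with different numbers gave -0.125 to 0.191. Across all genes this gives no sign that the numbers pair the samples, but it cannot exclude pairing. Some sebocyte genes did go with the number in the long-term libraries. Far2 was at 31.5 and 25.5 TPM in the libraries numbered 2 against 1.86 and 3.04 TPM in those numbered 1. Cidea was at 21.3 and 17.6 against 2.88 and 2.98 TPM, while Pparg and Fabp4 did not go with the number. Whether same-numbered libraries share a preparation was not tested. In groups of 2 libraries the deviations mirror each other, so the long-term r is a single independent value. With the number as a replicate block limma called 282 genes at 24 h (354 without it), 1417 at 48 h (1765), 19 for 48 h against 24 h (5) and 284 long-term (1). For EpiSCs it called 5301 by the title number and 4752 by the description number. The deposited TPM hold no counts, so what depth limits could not be measured.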

Other observations

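The test of where genes changed at both fasting times lie in the long-term libraries was chosen after the short fasting result was seen. A hypothesis is that genes raised by short fasting are also raised after long-term alternate-day fasting. The median of the 161 genes higher at both times lay above 100% of 10000 matched random lists, which leave out the correlation between genes. This is consistent with the hypothesis, although 0 of them passed the limma threshold long-term and 29 against 9 were higher and lower at an unadjusted p under 0.05. The same hypothesis for the 88 genes lower at both times is not borne out, as their median lay above 92.2% of random lists. The tables share no libraries, and other differences between the experiments, such as age and batch, were not tested.

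Cebpb, Fosl1 and Krt16, genes of acute keratinocyte responses, were near the floor in fed HFSCs of the short experiment and high in telogen, EpiSC and long-term libraries, the last from a table that shares no library with the others. Sostdc1, an inhibitor of BMP and Wnt signals that bulge cells and dermal papilla both express, was at 606 to 749 TPM in the fed libraries of the short experiment. It was at 870, 423 and 141 TPM in the 24 h libraries and at 63.7 to 210 TPM in the 48 h libraries. The sebocyte gene Cidea was at 27.0, 21.5 and 3.33 TPM in the 24 h libraries, at 4.76 to 5.18 TPM in the fed ones, and at 21.3 and 17.6 TPM in long-term fasted library 2 and fed library 2. In 24 h libraries 1 and 2 the sebocyte genes Pparg, Scd3 and Awat1 were at 0 TPM. There Far2 was at 0 and 7.64 TPM and Awat2 at 3.96 and 4.21 TPM. The antigen presentation gene Cd74 was at 50.5 to 153 TPM in the long-term libraries and 33.7 and 34.3 TPM in telogen against at most 16.9 TPM in any library of the short experiment. The haemoglobin transcript Hba-a2 was at 54.01 and 77.7 TPM in telogen, 72.6 TPM in long-term fasted library 1, 26.4 to 30.1 TPM in the other long-term libraries and at most 21.1 TPM in the short experiment.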
